A study of Mus musculus with 12 samples.

How the data were processed

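Confluent wild-type C57BL/6 mouse embryonic fibroblasts, primary connective-tissue cells grown from embryos, were synchronised with Dex and then either kept at 35 °C or moved to 38.5 °C for 2 h, starting 24 h after Dex. The sample annotation used here holds no time after Dex for the cells kept at 35 °C. A difference in harvest time therefore cannot be told apart from warming. The labels call the warm step WTS. RNA-seq and ribosome profiling were each applied to both treatments with 3 replicates, which gave 12 libraries in 4 groups. The series design text states that the experiments were independent, and no label says that a replicate number marks a culture or day shared between treatments.

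Per the labels' protocols, RNA libraries were made with a stranded total RNA kit, and cells were lysed in the presence of cycloheximide, which holds ribosomes on the mRNA. Footprint libraries were made by linker ligation, rRNA depletion, reverse transcription, circularisation and PCR. The submitters' processing notes name CASAVA 1.8, STAR 2.7.0 and the mm10 build. The read counter, the transcript annotation release, the filters and the treatment of reads that fit several isoforms were not given in the sources used here. The authors deposited 1 table per library, with raw counts for each of 63759 transcript IDs and a length for 46419 of them. IDs without a length held 0 counts in total and were left out. The unit of the length was not stated, its median was 368, and lengths with remainders of 0, 1 and 2 after division by 3 numbered 15432, 15345 and 15642.

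The files do not pair the transcript IDs with gene names, and 0 of the IDs occurred in the 2 tables of mouse gene names at hand. All 31 gene lists chosen before the data were examined, their set tests, the genes to be named in every comparison and the shares of counts in mitochondrial, ribosomal-protein and nuclear-retained transcripts therefore could not be evaluated. With no names, only 2 IDs that rose and 2 that fell were printed. They were chosen after the values had been seen. In each direction the ID with the largest footprint change among calls made without a replicate block was taken, followed by the ID with the largest change in the footprint fit with the block from another read-sharing group. Both needed a mean of at least 1 CPM in footprints, treatment groups that did not overlap in footprint CPM, and a test in both assays. The last requirement was added after an ID that was tested in footprints alone had come up first among those that fell.

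Neighbouring IDs often had near-identical counts, as isoforms that receive the same reads would. Pairs were compared where both IDs held a mean of at least 10 counts over the 12 libraries, with 1 added to each count. Of such pairs 1 row apart, 31.7% had counts within 1.25 times of each other in all 12 libraries, against 0.0121% of such pairs 1000 rows apart. IDs within 30 rows that met the same minimum and ratio were joined into read-sharing groups, and the 27967 IDs tested in either assay formed 19361 groups. Counts of IDs are therefore larger than counts of separate transcripts, and values of single isoforms are uncertain. If IDs share reads in this way, library totals count a read once for every ID that received it.

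Each assay was tested alone with edgeR 4.0.16 in R 4.3.3, using the robust quasi-likelihood F test on the deposited counts, TMM scaling, filterByExpr by group and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. A change in translational efficiency, the ratio of footprints to RNA, was tested as the interaction of assay and treatment over all 12 libraries. These fits, without a replicate block, and the fits with the replicate number as a block were both specified before the data were examined, the first as the reported fit and the second as an alternative. Standard errors were computed from the fold change and F. CPM values of single IDs are counts scaled to a fixed library total without TMM, and fold changes are log2 of warm over 35 °C. The log2 CPM behind principal components, pairing correlations, deviations of number 1 and changes within a numbered pair were TMM-scaled. Footprint TMM factors were 0.773 and 0.816 for number 1 and 1.12 to 1.14 for the others. Printed CPM of number 1 and of the others are therefore not on the scale of the fits.

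Same-numbered libraries deviated together from their group means. The correlations across IDs were 0.840, 0.485 and 0.585 for numbers 1, 2 and 3 in RNA and 0.853, 0.606 and 0.654 in footprints, all above the limit set for pairing. The pairing comes from these correlations and not from the labels, and it rests on number 1 against the others: the difference between numbers 2 and 3 correlated at -0.110 in RNA and -0.0192 in footprints between the treatments. Number 2 of a treatment against number 3 of the other gave 0.571 and 0.638 in RNA and 0.632 and 0.646 in footprints. Each was above the value for number 2 with itself, so these 2 numbers were not told apart. Values with the block are given beside those without it wherever the call or the count differs. Numbers of calls had been seen together with the correlations. Libraries of a group differed beyond sampling noise, and none was counted as a duplicate. The chi-square per degree of freedom lay between 27.5 and 94.7 for pairs with number 1, over both assays. Between numbers 2 and 3 it was 1.31 without warming and 1.33 with it in footprints, and 4.20 and 1.55 in RNA. Footprint fits to numbers 2 and 3 alone therefore rest on libraries that were close to sampling noise within a treatment. Parts of 1 culture could also be this close, so numbers 2 and 3 may not be independent replicates, although the design text calls the experiments independent. In that case n = 3 counts libraries, and calls from fits to these 2 numbers, or led by them, would be overstated.

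The tests were run on simulated counts for the same libraries, with 100 IDs changed 1.5-fold and 100 changed 2-fold. Changed IDs were drawn from those with a mean count of at least 50. Simulated means were common to same-numbered libraries of an assay, and the spread came from fits with a number block. Pairing by number was thus built in, so the recovered shares cannot show that the block suits the real libraries. For RNA (26997 IDs), the fit without the block recovered 0% of either size, and the fit with the block 73% and 98%, with 11 false calls. For footprints (26621 IDs) the shares were 0% of either size without the block and 69% and 96% with it, with 5 false calls. For the interaction (25886 IDs) they were 0% of either size without the block and 0% and 18% with the number as a block. They were 16% and 78%, with 4 false calls, with a separate number block in each assay, which was added after seeing the data. The interaction counts were simulated from that same model.

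Alternatives were DESeq2 1.42.0 and its size factors, upper-quartile and total-count scaling, limma 3.58.1 with voom, other count filters, thinning to equal totals, a test against a 1.2-fold change, a block per culture, each library or number left out, and contrasts from the 12-library fit. Added after seeing the data were the collapse to 1 ID per read-sharing group, a block of 2 levels (number 1 against the others), numbers 2 and 3 alone, the 10 most abundant IDs left out, a number block within each assay, the correlation of fold changes with the block, when collapsed, between different numbers and over other splits, and every alternative of the fits with the block. Comparisons of single values used an exact two-sided permutation test, in which 3 against 3 cannot give a p below 0.1.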

Results

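The data comprised total counts per library of 8686742 to 12212227 in RNA-seq and 8449802 to 82560281 in ribosome footprints of mouse embryonic fibroblasts kept at 35 °C or warmed to 38.5 °C for 2 h. In RNA, the 3 libraries at 35 °C held 9859237, 11072158 and 11400423 counts and the 3 warm libraries 8686742, 9911235 and 12212227. In footprints, these were 23393113, 8449802 and 9959827 at 35 °C and 82560281, 9459723 and 13987481 after warming, so replicate 1 was the deepest of each group. Between 31750 and 34845 transcript IDs had at least 1 count in a library. The series design text places the warm step in the rising phase of Per2, a gene of the circadian clock, and the comparisons ask which transcripts and which ribosome footprints differed after it.

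The libraries numbered 1 stood apart from numbers 2 and 3 in both assays. The first principal component held 70.1% of the variance in RNA and 72.3% in footprints and separated number 1 from the others, while the second held 12.2% and 13.1% and separated the treatments. Number 1 was present once in each group, so this division was balanced over treatment.

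**Figure D1:**
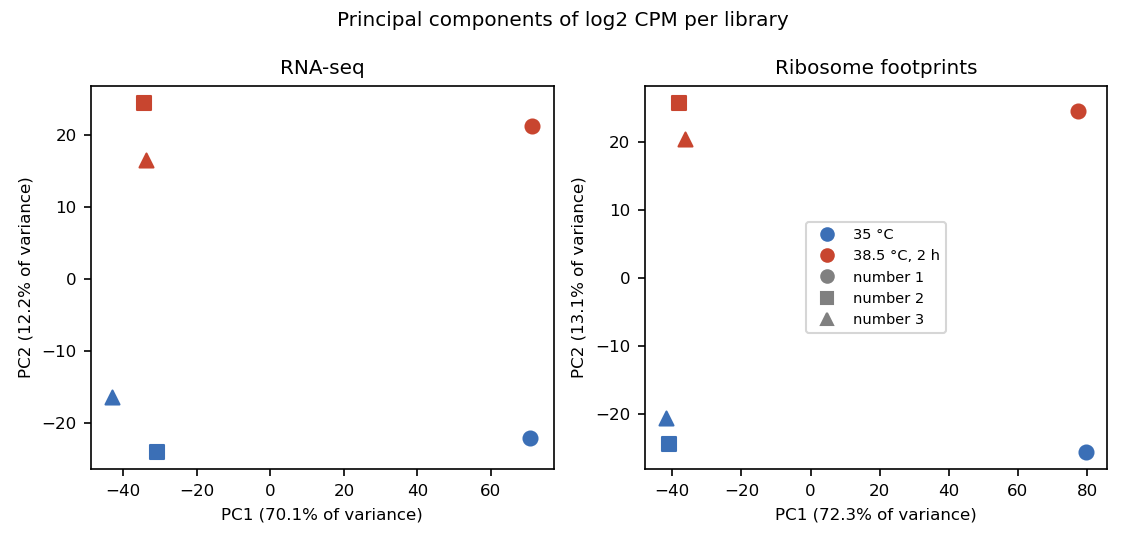
Principal components of log2 CPM for the 6 RNA-seq and the 6 footprint libraries, with 1 point per library marked by treatment and replicate number and each axis giving its share of the variance. Libraries numbered 1 lie apart on the first component (70.1% and 72.3% of the variance), and warm and 35 °C libraries lie apart on the second.

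In RNA, uc033jih.1 and uc008vfx.1 rose and uc007obo.1 and uc009gvt.3 fell in the fit with the replicate number as a block. The ID uc033jih.1 went from 6.53 ± 1.27 to 25.3 ± 2.11 CPM (SD, n = 3 each), a log2 fold change of 1.94 ± 0.14 (SE; edgeR adjusted p = 1.40e-34 with the block). With the block few residual degrees of freedom remain, so adjusted p-values of this fit lean on variance shared across IDs. Their sizes are not comparable between RNA and footprints. The ID uc008vfx.1 rose from 12.5 ± 0.869 to 27.9 ± 1.49 CPM (SD, n = 3), by 1.13 ± 0.12 on the log2 scale (SE; edgeR adjusted p = 3.29e-16 with the block). The ID uc007obo.1 went from 50.1 ± 9.75 to 22.6 ± 1.31 CPM (SD, n = 3), a log2 fold change of -1.17 ± 0.11 (SE; edgeR adjusted p = 2.97e-22 with the block), and uc009gvt.3 from 46.2 ± 6.64 to 27.4 ± 1.56 CPM (SD, n = 3), a log2 fold change of -0.77 ± 0.10 (SE; edgeR adjusted p = 5.11e-10 with the block). Without the block their edgeR adjusted p-values were 0.108, 0.152, 0.281 and 0.688, at log2 fold changes of 1.93, 1.13, -1.17 and -0.78. DESeq2 without the block gave adjusted p-values of 4.01e-11, 5.22e-06, 1.12e-05 and 0.0340, and the edgeR contrast from the 12-library fit without a block gave 0.000912 for uc033jih.1 and 0.0101 for uc007obo.1 and called neither of the other named IDs.

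Without the block, edgeR called 0 of 27223 IDs in RNA, with 1119 at an unadjusted p under 0.05, while DESeq2 called 45 and limma-voom 0. If no ID changed, a share of 0.05 of the IDs would have such a p on average, and 1119 is below that share. When 1 RNA library was left out, edgeR again called 0, with 592 to 1606 at an unadjusted p under 0.05. With the replicate number as a block, edgeR called 1265 IDs, of which 624 rose and 641 fell, while DESeq2 with the block called 207 and limma-voom 1241. Total-count scaling gave 681 that rose and 452 that fell. The median size of a called change was 0.49 on the log2 scale, and 39 IDs rose and 47 fell at least 2-fold. Collapsed to 1 ID per read-sharing group, 839 of 18733 groups were called, 423 higher and 416 lower, with 20 and 30 at least 2-fold. With the block, there were 379 calls without number 1, 600 without number 2 and 1202 without number 3, of which 363, 530 and 772 were among the 1265. Within numbers 2 and 3 alone, with no block, 344 IDs were called, and number 1 alone has 1 library per treatment and allows no test.

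In ribosome footprints, the same 4 IDs moved in the directions seen in RNA. The ID uc033jih.1 rose from 4.08 ± 0.969 to 23.7 ± 4.0 CPM (SD, n = 3), a log2 fold change of 2.52 ± 0.14 (SE; edgeR adjusted p = 0.00771), and uc007obo.1 fell from 54.0 ± 9.23 to 17.1 ± 3.68 CPM (SD, n = 3), a log2 fold change of -1.69 ± 0.12 (SE; edgeR adjusted p = 0.0106). Both adjusted p-values were 6.23e-08 with the block in edgeR. The ID uc008vfx.1 rose from 24.1 ± 8.0 to 81.7 ± 13.7 CPM (SD, n = 3), a log2 fold change of 1.74 ± 0.10 with the block (SE; edgeR adjusted p = 1.77e-07) and 1.69 without it (edgeR adjusted p = 0.576). The ID uc009gvt.3 fell from 4.67 ± 1.8 to 1.72 ± 0.887 CPM (SD, n = 3), a log2 fold change of -1.74 ± 0.26 with the block (SE; edgeR adjusted p = 0.00166) and -1.59 without it (edgeR adjusted p = 0.545). Its footprint counts were low, between 23 and 79 per library.

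**Figure D2:**
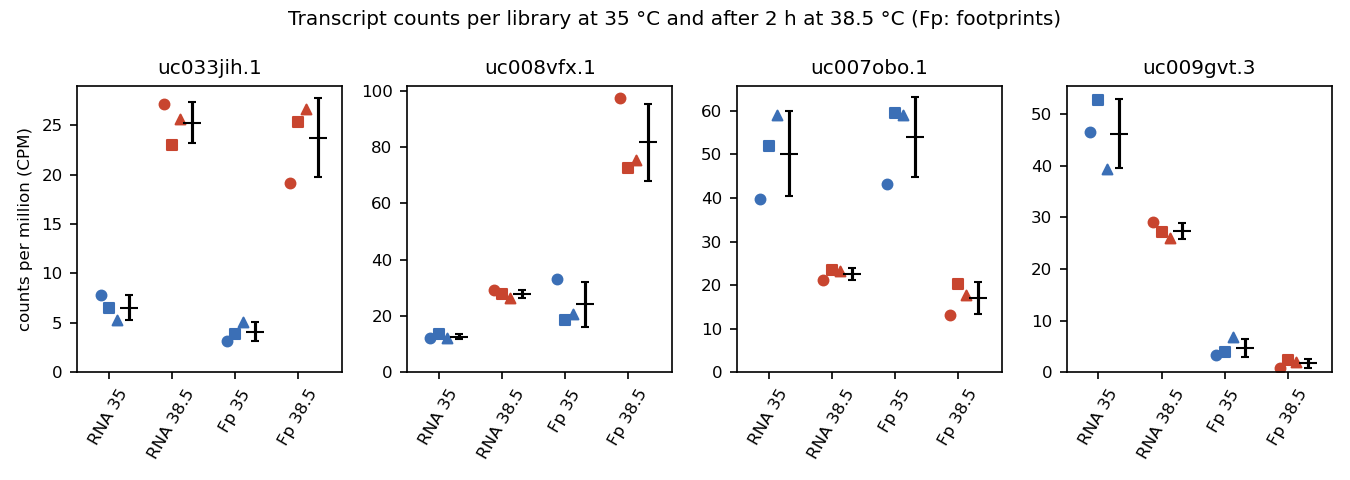
Counts scaled to the library total without TMM (CPM) of the 4 named transcript IDs in each RNA-seq and footprint library, by treatment, with 1 point per library (circle, square and triangle for numbers 1, 2 and 3) and a bar for the mean and SD of 3 libraries. For uc033jih.1, footprints rose from a mean of 4.08 to 23.7 CPM, and for uc007obo.1 they fell from 54.0 to 17.1 CPM.

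Without the block, edgeR called 8 of 26920 IDs in footprints, 4 higher and 4 lower, with 1787 at an unadjusted p under 0.05. The number at an unadjusted p under 0.05 was 1027 to 2383 without 1 footprint library and 656 with total-count scaling. The 1787 exceed a share of 0.05 of the IDs tested, and the 656 do not. DESeq2 without the block called 74 IDs, these 8 among them, and limma-voom the same 8. The 8 IDs formed 2 read-sharing groups, those of uc033jih.1 and uc007obo.1, each of 4 IDs with near-identical counts. Leaving out any 1 of the footprint libraries other than replicate 1 at 35 °C gave 0 calls, and total-count scaling gave 0. In these fits the log2 fold change stayed between 2.44 and 2.60 for uc033jih.1 and between -1.75 and -1.66 for uc007obo.1, with edgeR adjusted p-values of 0.0532 to 0.411. With the block, 1748 IDs were called in edgeR, 940 higher and 808 lower, while DESeq2 called 531 and limma-voom 1932, and upper-quartile scaling gave 784 higher and 1013 lower. The median size of a called change was 0.53 on the log2 scale, and 45 IDs rose and 98 fell at least 2-fold. As read-sharing groups, 1146 of 18528 were called, 625 higher and 521 lower, with 31 and 65 at least 2-fold. With the block, there were 2830 calls without number 1, 1660 without number 2 and 1727 without number 3. Of these, 1372, 1121 and 1131 were among the 1748. Numbers 2 and 3 alone gave 3007 with no block, from footprint libraries that were close to sampling noise within a treatment.

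Across the 26176 IDs tested in both assays, the log2 fold changes in RNA and footprints correlated at r = 0.583 (Spearman's rho 0.554, covariance 0.0426). IDs are not independent replicates, and RNA and footprint libraries of a number can share the noise of a culture. Between RNA and footprint differences of the same number, r was 0.318, 0.324 and 0.378 for numbers 1, 2 and 3 (mean covariance 0.0441). Between RNA of a number and footprints of another, the 6 values of r lay between 0.210 and 0.378 (mean covariance 0.0383). Among the 17900 read-sharing groups tested in both assays with the block, 197 were called higher in both and 194 lower in both, where independent lists of these sizes would share 14.4 and 11.7, a value that leaves out noise common to both assays, and 0 were called in opposite directions. Of the 825 groups called in RNA, 96.4% had the same sign in footprints, of the 1132 called in footprints 95.6% had the same sign in RNA, and over all groups the share was 68.9%.

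**Figure D3:**
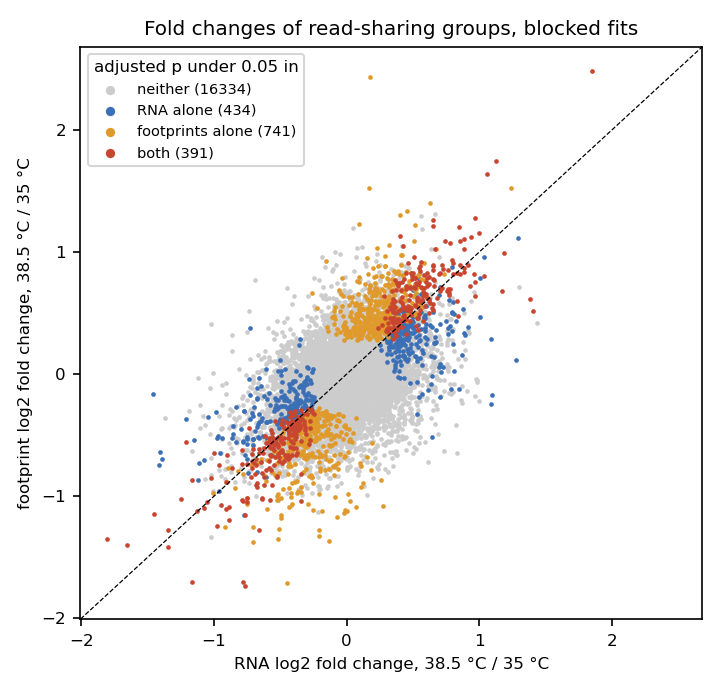
Log2 fold change (warm over 35 °C) in RNA-seq on the x axis and in ribosome footprints on the y axis for 17900 read-sharing groups, from the fits with the replicate block and coloured by call. Groups called in both assays number 391 and lie in the 2 quadrants where the signs match, 434 were called in RNA alone and 741 in footprints alone.

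Translational efficiency gave 0 calls among 26176 IDs in edgeR without the block, with 257 at an unadjusted p under 0.05, and 0 with the replicate block, with 642. The 257 became 217 to 437 when 1 library was left out and 83 with total-count scaling, again with 0 calls. All of these counts, the 642 included, are below a share of 0.05 of the IDs tested. DESeq2 and limma-voom without the block also called 0. The interaction estimates with the block were 0.58 ± 0.21 (SE) for uc033jih.1, 0.58 ± 0.32 for uc008vfx.1, -0.53 ± 0.17 for uc007obo.1 and -1.04 ± 0.34 for uc009gvt.3 on the log2 scale, each with an edgeR adjusted p of 0.9999. Without the block and without 1 footprint library, the estimate for uc008vfx.1 went from 0.55 to 1.16, 0.31 and 0.35 without replicates 1, 2 and 3 at 35 °C and to 0.21 without warm replicate 1, and that for uc009gvt.3 from -0.87 to -0.45 without warm replicate 1. Such fits hold number 1 unequally over the treatments, so its offset enters the estimate. At 35 °C and after warming, footprint CPM in number 1 were the highest for uc008vfx.1 (33.3 and 97.4) and the lowest for uc009gvt.3 (3.38 and 0.727). In simulated data the fit recovered 18% of 2-fold changes with the block and 0% without it. A fit with a separate number block in each assay, added after seeing the data, recovered 78% of 2-fold and 16% of 1.5-fold changes. The counts were simulated from that same model, so this recovery holds only where its assumptions do. On the deposited counts this fit also gave 0 calls in edgeR, with 1256 at an unadjusted p under 0.05 and edgeR adjusted p-values of 0.857 for uc033jih.1 and 0.308 for the other 3 named IDs. The 1256 are also below a share of 0.05 of the IDs tested. Numbers 2 and 3 alone, which may not be independent replicates, gave 3 calls, all higher.

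The 10 most abundant IDs held 11.1 ± 1.60% of RNA counts at 35 °C and 10.98 ± 1.19% after warming (SD, n = 3; exact permutation p = 0.8). In footprints they held 16.1 ± 2.37% and 16.2 ± 2.21% (SD, n = 3; exact permutation p = 1). The smallest p this design allows is 0.1. This test ignores the replicate numbers, and number 1 held the largest share in every group. Within numbers 1, 2 and 3, warm minus 35 °C was -0.641, 0.434 and -0.237 points in RNA. In footprints it was -0.0905, -0.0581 and 0.353 points.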

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

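The reported fits without a block and most alternatives were chosen before the data were examined. Chosen after seeing the data were the alternatives of the block fits, the read-sharing collapse, the 2-level block, the number block within each assay, the 10 most abundant IDs left out, numbers 2 and 3 alone, and the correlation of changes with the block. No fold change of a named ID changed sign under the alternatives run. The difference in the share of the 10 most abundant IDs, which passed no test, did so without 1 library, from -0.148 points to between -0.824 and 0.774 in RNA and from 0.0681 to between -1.21 and 1.42 in footprints. Leaving out 1 library makes number 1, with its larger share, unequal over the treatments, so these shifts do not measure warming alone. With the block and upper-quartile scaling, more footprint IDs fell (1013) than rose (784). RNA calls, 0 as reported, became 45 with DESeq2, 1265 with the replicate block, 1199 with the 2-level block, 9 from the 12-library fit and 344 for numbers 2 and 3 alone. Footprint calls, 8 as reported, became 0 with total-count scaling, 74 with DESeq2, 1748 with the replicate block, 3140 with the 2-level block, 23 from the 12-library fit, 3007 for numbers 2 and 3 alone and 2 when collapsed, and 0 to 8 without 1 library. Translational efficiency gave 3 calls for numbers 2 and 3 alone and 0 under every other alternative run, the replicate block included. With the replicate block, RNA calls became 207 with DESeq2, 156 against a 1.2-fold change, 839 when collapsed and 379 to 1202 without 1 number. Footprint calls became 2866 with no count filter, 531 with DESeq2, 362 against a 1.2-fold change, 1146 when collapsed and 1660 to 2830 without 1 number. Fewer groups than IDs were tested in the collapsed fits, and leaving out 1 library without the block made number 1 unequal over the treatments. How far each of these matters, and the cause of the other changes, was not tested. The correlation of RNA and footprint changes was 0.618 for IDs with at least 10 counts in every library and 0.452 to 0.505 without 1 number. Among the alternatives for the 4 named IDs, 241 values kept their side of the threshold, 24 passed it and 12 no longer did. The set tests, the shares by gene class and the exclusion of mitochondrial transcripts were not run, because the IDs could not be matched to gene names here. Thinning to the smallest total of each assay kept every count of calls within 1.5 times.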

Other observations

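The tests of library preparation and of listed length, and the correlations over other splits, were chosen only after the result was seen. Between number 1 and numbers 2 and 3, with treatment as a covariate, edgeR called 12021 IDs in RNA and 14030 in footprints. Of 17900 read-sharing groups, 1191 deviated by over 1 on the log2 scale in both assays with the same sign. Thinning to equal totals left 77.1% as many footprint calls and 96.6% as many RNA calls, which argues against unequal depth as the whole cause. A fault of library preparation in 1 assay as the whole cause is argued against by the correlation of the deviation between RNA and footprints across groups (r = 0.746). A fault in 1 assay on top of a difference common to both would still allow a high r and stays open. A loss by listed length is argued against by the 0.621% of variance that length classes explained at most. Different cells, another culture day or another handling of both assays may lie behind the deviation of number 1 and stay open, and no biological explanation was tested.

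Among 16914 IDs with at least 50 counts in each of the other 4 footprint libraries, 5 IDs in 3 read-sharing groups had 0 counts in both footprint libraries numbered 1. These 5 had 93 to 1589 counts in the other 4. A count of 0 allows up to 0.128 CPM at 35 °C and 0.0363 CPM after warming, for counting error only, and the same IDs had 79 to 1780 RNA counts in the libraries numbered 1. In the other direction, 10 IDs in 6 groups had at least 50 counts in both footprint libraries numbered 1 and at most 1 in each of the other 4, and 8 of them were also at 10 or more in both RNA libraries numbered 1 and at most 2 in the other RNA libraries.

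For all 4 named IDs the footprint change was larger than the RNA change. The IDs had been picked for a large footprint change, which favours that order, so they are no evidence for it, and they only prompted the hypothesis that translation may add to the change in RNA. Groups were selected on the mean change of both assays in 1 numbered pair, 200 of 14683, and evaluated in the other pairs. The median changes in RNA and footprints were 0.43 and 0.54 when selected on number 1, 0.39 and 0.58 on number 2, and 0.54 and 0.65 on number 3, so the ratio was 1.195 at its lowest, and footprints changed more in 131, 134 and 133 of the 200. The hypothesis was found and tested on the same libraries. Numbers 2 and 3 were not told apart, so the pairs used for selection and evaluation are not shown to be independent. Over all IDs without the block, footprint changes had the wider spread (SD 0.289 against 0.253 in RNA). The share of all 14683 groups in which footprints changed more was not computed. A compression of RNA changes by total RNA outside the translated pool may give the same ratio and was not tested, and no single ID passed the test of translational efficiency apart from 3 for numbers 2 and 3 alone.

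The groups of 3 against 3 make 10 splits, and 4 of them part every numbered pair, which is too few for a share under 0.05. Without the block, the real split gave 0 calls in RNA and 0 in translational efficiency, the highest of the other splits gave 0 in each, and 10 of the 10 splits were as large. In footprints the real split gave 8, the highest other 0, and 1 of 10 was as large. With the block, the real split gave 1265 calls in RNA and 1748 in footprints, the highest other gave 0 in each, and 1 of 4 was as large. The other 3 of these 4 splits exchange the treatments within 1 numbered pair and so still hold part of the treatment difference. The correlation of RNA and footprint fold changes with the block was 0.579 in the real split and at most 0.260 in those 3. Without the block it was 0.583 in the real split and 0.696 to 0.727 in the 4 splits that put both treatments of number 1 on the same side, so the way number 1 stands apart gave a higher correlation than the treatment did.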
